A study of Mus musculus with 6 samples.

How the data were processed

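Thyroid RNA of 6 mouse samples at postnatal day 15 was measured on Affymetrix mouse expression arrays, 3 from animals heterozygous for Slc26a4 and 3 from knockouts. Per the labels' protocols, the thyroid was microdissected, RNA was isolated with a Qiagen kit and labelled after amplification by NuGEN's Ovation method, with streptavidin named as the label. The arrays are named here by their genotype and by the sample number in their titles, heterozygous 1, 3 and 5 and knockout 2, 4 and 6. The groups share no sample number, so no pairing was fitted. The deletion's position within Slc26a4, the animals' sex and the number of animals behind each RNA are not given in the sources used here.

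The deposited values are linear intensities, 1 per probe set and array, called signals below. They came from GCOS, the array maker's operating software, per the submitters' processing notes, and its version and settings are not given in the sources used here. On each of the 6 arrays the mean of the signals, after trimming 2% of the values at each end, was 500.002. The arrays had therefore been scaled to a common mean, and the values were used with that scaling. Detection calls were not used here, and the scanner images were not analysed. Any difference that moved most transcripts in the same direction would have been removed by this scaling.

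Probe sets were named from the platform annotation of the array, and 34958 of the 45101 probe sets carried 1 gene symbol, 932 several and 9211 none. Symbols were checked through gene identifiers against the RefSeq annotation of the mouse assembly GRCm38.p6, which altered 0 of them. Only probe sets with 1 symbol are named. A probe set without a symbol was counted among those tested and is not named here. Duox2, Foxe1 and Calca were not analysed here. No genome build is named for the array, so no coordinates are given, and the RefSeq order of genes was used only to find the neighbours of Slc26a4.

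The signals were put on a log2 scale as log2(signal + 16.7), where 16.7 is the 25th percentile of all values of the 6 arrays pooled. Fold changes on this scale understate the change of dim genes. The 64 control probe sets were left out. The 27022 of the 45037 remaining probe sets whose mean log2 value lay above the 40th percentile were tested, a limit that corresponds to a signal of 43.5. As a measure of background, 27 control probe sets for bacterial transcripts were used, and the brightest of their values on any array was 22.9.

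Groups were compared with limma 3.58.1 in R 4.3.3, by lmFit and eBayes with an intensity trend, and p-values were adjusted by the Benjamini-Hochberg method over the 27022 probe sets with a threshold of 0.05. Every adjusted p for a probe set below comes from limma. Welch's test on the same log2 values, as a count only, was the other tool. Each gene of a list was represented by its tested probe set of the highest mean. Lists with at least 5 tested genes, 25 in all, were tested with limma's camera at a preset correlation of 0.01 between genes and adjusted over the 25 lists. Camera with an estimated correlation and fry were run beside it. A gene's level is given as the mean signal ± SD of the 3 arrays of a group, and a single value compared between groups by an exact permutation test cannot reach a p below 0.1 with 3 arrays against 3.

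The grouping, the tests, the gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. The rule named Slc26a4. It then named, in each direction, up to 12 genes past the threshold whose groups did not overlap, ranked by fold change. Where fewer qualified, it filled the 12 with genes of the smallest unadjusted p among those with a fold of at least 1.5 and no overlap. It also named the 2 to 4 members of each list with the smallest unadjusted p, together with Tg, Slc5a5, Tshr, Dio1, Nkx2-1 and Pax8. Other genes named below were chosen after their values were seen.

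The alternatives were quantile and cyclic loess normalization, pseudocounts of 0.25 and 4 times the one used, no filter and a filter at the 60th percentile, eBayes without a trend and with robust fitting, array weights, and each array left out in turn. For the lists, the mean of all probe sets of a gene was an alternative as well. Another 3 settings were added after seeing the data. They left out heterozygous 1 with knockout 6, left out knockout 4 with knockout 6, and took sample numbers 1 to 3 against 4 to 6 as a block.

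The fit was tested on simulated data for this comparison, drawn for the 27022 probe sets from their real means and residual spreads, with 200 probe sets moved by known folds, 50 per fold. It recovered 12% of those moved by 1.5-fold, 50% at 2-fold, 78% at 4-fold and 90% at 8-fold, and called 7 that had not been moved. With no probe set moved it called 0. Of the simulated probe sets that were not moved, 5.17% had an unadjusted p under 0.05, against 0.511% of those tested on the real arrays. The simulation thus differs from the real arrays, and these recovery rates need not hold for them. In the arrays themselves, the median standard error of a log2 difference was 0.19, and the median 95% confidence interval reached 0.43 to either side. The number of arrays limits this precision.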

Results

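Gene expression was measured in microdissected thyroid of mice at postnatal day 15, with 3 arrays from Slc26a4 heterozygotes and 3 from Slc26a4 knockouts. Slc26a4 encodes pendrin, an anion exchanger that carries chloride, iodide and bicarbonate and is found at the apical membrane of thyroid follicular cells. The comparison asked which transcripts differ in the thyroid when pendrin is lost, with heterozygous mice as the controls. Levels are array signals on a linear scale, given as the mean ± SD of a group (n = 3 arrays). The median signal of an array lay between 78.1 and 103.6, and between 67.5% and 73.8% of its probe sets were brighter than the background of 22.9 set by bacterial control probe sets. The labels do not say that each array came from a separate animal, so p-values measure the spread between these samples. That spread may be technical in part. Xist read 77.6, 34.3 and 5442 on knockouts 2, 4 and 6 (probe set 1436936_s_at), and Dntt read 6.09, 1779 and 22.7 (1449757_x_at). Pth read 165.2, 10356 and 9702 on heterozygous 1, 3 and 5. These values argue against the 3 arrays of either genotype being repeats of 1 RNA.

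Slc26a4 itself read under background in both genotypes. Its probe set, 1419725_at, read 5.0, 4.59 and 12.1 on heterozygous arrays 1, 3 and 5 and 7.29, 2.10 and 15.7 on knockout arrays 2, 4 and 6, all under the background of 22.9. The means were 7.23 ± 4.24 and 8.36 ± 6.86, and the probe set fell under the filter and was not tested. Since the heterozygous arrays already read under background, a loss could not show, and this probe set does not check the genotypes. The labels also do not say which part of the gene was deleted. The related exchanger Slc26a7 was bright in both, at 8382 ± 785 in heterozygous and 8136 ± 806 in knockout thyroid by probe set 1436279_at.

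None of the thyroid transcripts named in advance passed between knockout and heterozygous glands (limma), and the intervals of several leave room for sizeable differences. Thyroglobulin (Tg), the protein on which the hormones are made, read 12918 ± 768 in heterozygous and 12544 ± 708 in knockout samples, a log2 difference of -0.04 with a 95% interval of -0.20 to 0.12. The iodide transporter Slc5a5 read 2075 ± 758 and 2412 ± 883 by its brighter probe set, 1436239_at, with a log2 difference of 0.22 and an interval of -0.51 to 0.96. The deiodinase Dio1 read 4028 ± 740 and 3830 ± 1185, with an interval of -0.61 to 0.41. The thyroid transcription factors Pax8 (3012 ± 345 and 2725 ± 255) and Nkx2-1 (179.4 ± 12.9 and 166.8 ± 7.67) also differed by less than could be told from the spread between arrays. The thyrotropin receptor Tshr read 909.3 ± 159.8 and 967.2 ± 247.8 by probe set 1442300_at and 321.9 ± 73.9 and 403.7 ± 103.4 by 1421999_at, where the interval was -0.25 to 0.86. The deiodinase Dio2 read 1894 ± 198 and 2849 ± 1090, a log2 difference of 0.52 that did not pass (limma, adjusted p = 1.0).

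Across the array, 0 of the 27022 probe sets tested were higher and 0 were lower in knockout thyroid by limma at an adjusted p of 0.05. At an unadjusted p under 0.05 limma had 138, of which 66 were higher and 72 lower, which is 0.511% of those tested where chance gives 5%. The other tool, which tested each probe set without limma's shared variance, also gave 0 higher and 0 lower, with 283 at an unadjusted p under 0.05. The 3 knockout arrays lay wholly above or below the 3 heterozygous arrays for 995 probe sets, or 3.68%, where chance gives 10%.

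The gene closest to a difference was Mucl1, which encodes a small mucin-like secreted protein. Its signal was 24.9 ± 12.7 in heterozygous and 150.4 ± 17.1 in knockout thyroid, a log2 difference of 2.05 ± 0.28 (SE) with an interval of 1.40 to 2.70. It was higher on all 3 knockout arrays than on any heterozygous array, and it did not pass (limma, unadjusted p = 8.8e-05, adjusted p = 1.0). The lowest of its heterozygous values, 10.9 on heterozygous 1, lay under the background. Among the lower genes Tmem65, which encodes a mitochondrial membrane protein, came first by p, at 164.5 ± 8.12 and 86.2 ± 5.54, a log2 difference of -0.82 ± 0.17 (SE; limma, unadjusted p = 0.0015, adjusted p = 1.0). Another probe set of Tmem65, 1452942_at, was far brighter and did not show it, at 4352 ± 247 and 4534 ± 309. Tmem18, a nuclear membrane protein whose gene is the 7th measured neighbour of Slc26a4 on the chromosome, read 498.6 ± 72.7 and 325.7 ± 37.2, a log2 difference of -0.59 ± 0.16 (SE; limma, adjusted p = 1.0).

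The other genes named by the same rule did not pass either and stood apart by smaller steps than Mucl1. Those with the higher knockout mean were Tbca, Serpina1b, Crlf2, Nfil3, Elovl3, Gfra1, Phf20, Gm16364, Cldn34c1, Serpina12 and H2-Oa, with log2 differences between 0.59 and 1.02. Serpina1b, a serum protease inhibitor, read 140.2 ± 39.4 and 302.7 ± 89.9, and its further probe set gave a log2 difference of 0.71 in the same direction. Nfil3, a transcription factor of the circadian and immune systems, read 199.3 ± 36.1 and 325.5 ± 69.6. Elovl3, a fatty acid elongase abundant in brown fat, read 149.5 ± 60.5 and 261.8 ± 28.9. Those with the lower knockout mean were Gkn3, Mcm3, Nebl, Kat6a, Strbp, Ogfod2, Cdk5, Pcsk1n, Nrap and Edaradd, with log2 differences between -0.78 and -0.59. The gastrokine Gkn3 read 165.6 ± 39.9 and 95.02 ± 15.3, and its further probe set gave -0.62. For Tbca, Gfra1, Phf20, Mcm3, Nebl, Kat6a, Strbp and Cdk5, brighter probe sets of the same gene gave log2 differences between -0.28 and 0.17, as with Tbca 1456205_x_at at 7030 ± 250 and 6997 ± 299. Dimmer tested probe sets of Cldn34c1 (105.0 ± 10.5 and 116.1 ± 23.1) and Edaradd (161.1 ± 46.5 and 166.9 ± 71.4) did not show it either. A dimmer one of Mcm3 gave 0.07, and a dimmer one of Nebl went the other way by 0.59 (38.0 ± 13.5 and 78.2 ± 68.4).

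**Figure D1:**
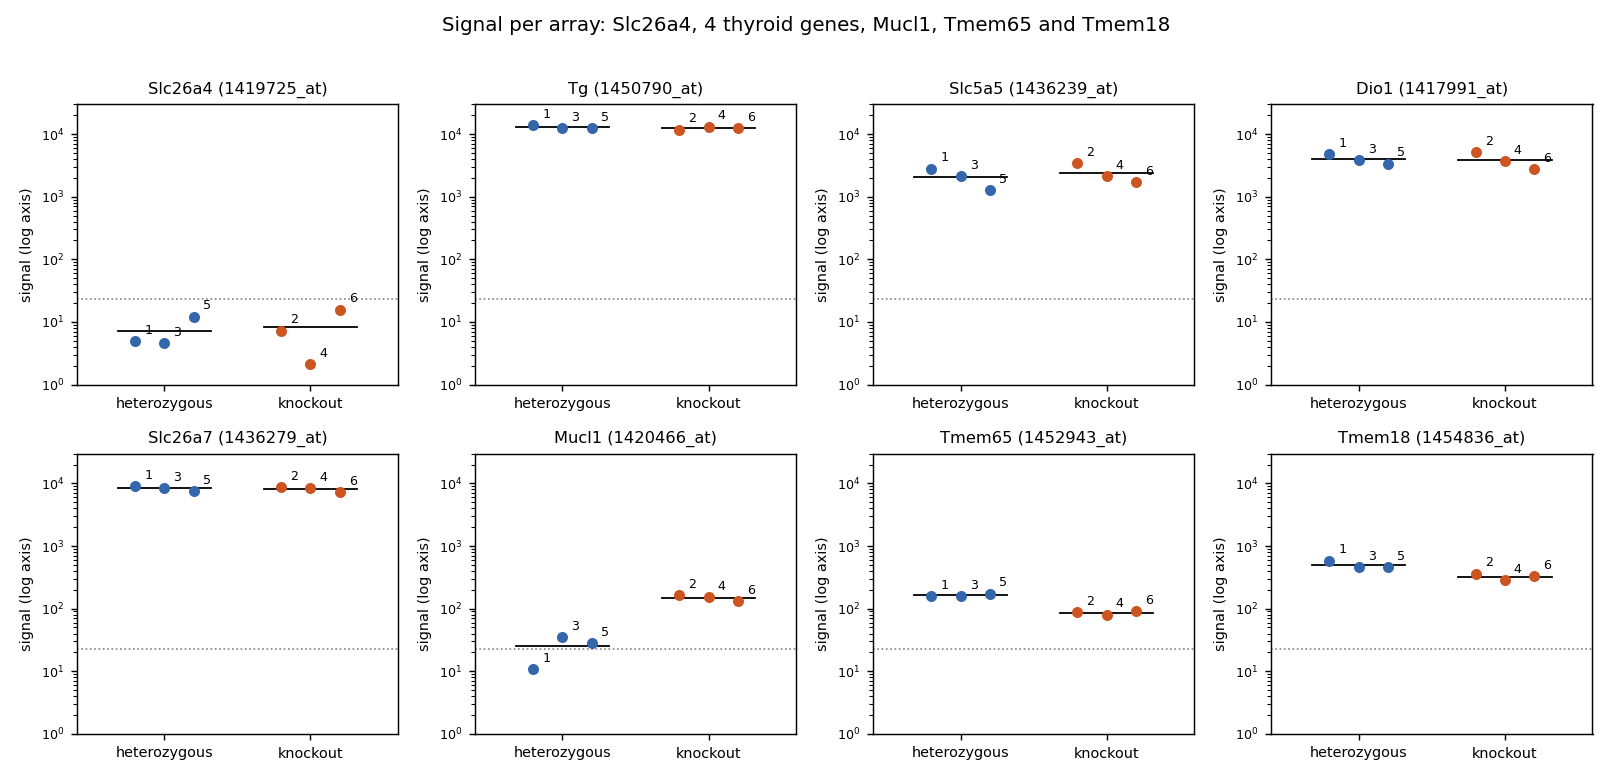
Signal per array (log axis) of Slc26a4, of Tg, Slc5a5, Dio1 and Slc26a7, and of Mucl1, Tmem65 and Tmem18, with heterozygous arrays in blue and knockout arrays in orange, numbered by sample; black bars are group means (n = 3 arrays) and the dotted line is the background of 22.9. All 6 Slc26a4 values lie under the background, Tg lies near 12918 and 12544, and Mucl1 lies at 150.4 in knockout against 24.9 in heterozygous samples.

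**Figure D2:**
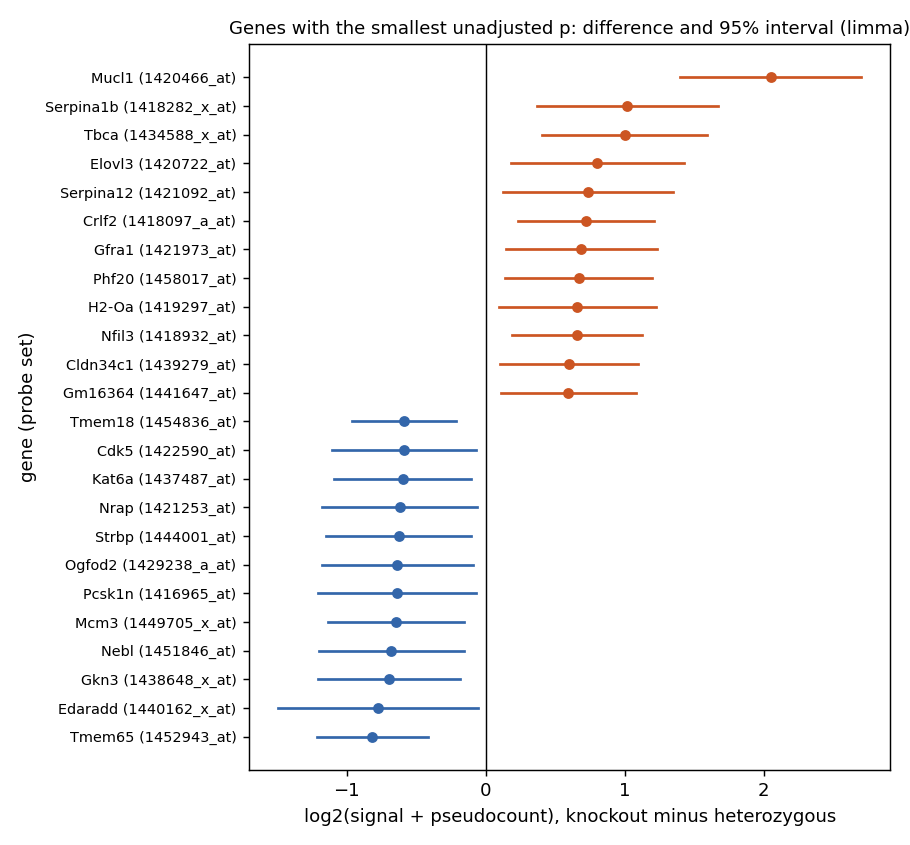
Log2 difference, knockout minus heterozygous, with its 95% confidence interval from limma, for the 12 genes per direction with the smallest unadjusted p among those with no overlap and a fold of at least 1.5. Mucl1 stands at 2.05 and the rest lie between -0.82 and 1.02; none passed at an adjusted p of 0.05.

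Among groups of genes fixed beforehand, the thyroid's own functions showed small shifts. No member of any list passed in limma over all probe sets tested, and 0 passed when adjusted over the list alone, where the smallest adjusted p was 0.104 for the erythroid heme enzyme Alas2 (198.5 ± 99.9 and 358.4 ± 108.5). Iodide handling and hormone synthesis had 16 tested genes, 6 higher and 10 lower in knockout, and did not pass (camera, adjusted p = 0.881). It passed as higher without heterozygous 1 (adjusted p = 0.0456, median 0.02) and without heterozygous 1 and knockout 6 (adjusted p = 0.00173, median 0.14). Dio2 and the potassium channel Kcnq1 (84.5 ± 6.96 and 105.4 ± 13.7) had its smallest p. Thyrocyte identity was lower as a group, with 14 of 16 genes lower and a median log2 difference of -0.10 (camera, adjusted p = 0.0237 with the preset correlation, adjusted p = 0.679 with an estimated correlation). Cdh1, the epithelial cadherin, read 6131 ± 766 and 5368 ± 715, and the kidney and thyroid cadherin Cdh16 read 2332 ± 413 and 1998 ± 668. This call was lost without heterozygous 1 (median -0.016, adjusted p = 0.767), heterozygous 3 (-0.098, 0.0846), knockout 4 (-0.075, 0.156) or knockout 6 (-0.0099, 0.679). The median was -0.19 without knockout 2 and without heterozygous 5, where the list still passed. Camera's direction turned to higher, without passing, without heterozygous 1 and with sample numbers 1 to 3 against 4 to 6 as a block. It also did so without heterozygous 1 and knockout 6 (median 0.087) and without knockouts 4 and 6 (0.079).

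Thyroid hormone signalling and response was higher as a group in knockout thyroid, with 10 of 14 genes higher and a median of 0.06 (camera, adjusted p = 0.0251, and adjusted p = 0.611 with an estimated correlation). Besides Dio2, its members with the smallest p were the receptor Rxra (902.3 ± 43.9 and 1028 ± 114) and the corepressor Hr (383.1 ± 52.9 and 462.0 ± 96.7). The call was lost without knockout 2 (median 0.053, adjusted p = 0.148), heterozygous 3 (-0.021, 0.785), knockout 4 (0.081, 0.123) or heterozygous 5 (0.048, 0.0509). Without heterozygous 1 the median was 0.12 and the list passed. Anion exchangers and channels did not pass (20 genes, camera, adjusted p = 0.985), with Slc4a2, a chloride and bicarbonate exchanger, at 591.2 ± 87.3 and 786.0 ± 134.1 and Slc26a10 at 58.4 ± 18.9 and 84.4 ± 27.2. Thyroglobulin proteolysis and lysosome did not pass (19 genes, adjusted p = 0.881), with the cathepsins Ctsl at 5513 ± 278 and 5168 ± 413 and Ctsz at 3344 ± 322 and 3702 ± 605. In the iodide, anion exchanger, proteolysis and cartilage lists the median was below 0 while the mean and the camera direction were above it. In the parathyroid and nerve lists the median and the camera direction were below 0 while the mean was above it.

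Of the stress and metabolic groups, antioxidant defence was higher in knockout thyroid, with 16 of 20 genes higher and a median of 0.05 (camera, adjusted p = 0.0237, and adjusted p = 0.611 with an estimated correlation). Nqo1, a quinone reductase, read 1257 ± 167 and 1527 ± 141, and Srxn1, which repairs peroxiredoxins, read 2031 ± 473 and 2341 ± 108. This call was lost without heterozygous 3 (median 0.020, adjusted p = 0.791), knockout 4 (0.033, 0.327), heterozygous 5 (0.070, 0.0547) or knockout 6 (0.053, 0.140). The list passed without heterozygous 1 (median 0.092) and without knockout 2 (0.076). The immediate early genes were lower, 16 of 21 with a median of -0.05 (adjusted p = 0.0287, and adjusted p = 0.611 with an estimated correlation), led by Fosb (83.6 ± 19.7 and 50.8 ± 23.0) and Egr1 (3223 ± 568 and 2712 ± 191). That call was lost without heterozygous 1 (median -0.017, adjusted p = 0.907), knockout 2 (-0.028, 0.516) or knockout 4 (-0.067, 0.123). The list passed without heterozygous 5 (median -0.088) and without knockout 6 (-0.11). Endoplasmic reticulum chaperones (16 of 20 lower, adjusted p = 0.0987), oxidative phosphorylation (34 of 47 higher, 0.0625) and glycolysis and hypoxia response (14 of 19 higher, 0.0525) did not pass. Oxidative phosphorylation passed in both directions. It passed as higher without heterozygous 1 (camera, adjusted p = 0.0337), knockout 2 (4.8e-09) or heterozygous 5 (3.8e-06), as under quantile normalization (0.0144) and array weights (2.3e-06). It passed as lower without heterozygous 3 (0.00616) and with sample numbers 1 to 3 against 4 to 6 as a block (3.1e-05). Without knockouts 4 and 6 its median was -0.17. The chaperones passed as lower without heterozygous 5 (adjusted p = 3.8e-06), with cyclic loess (0.0419) and with array weights (0.0348), and as higher without heterozygous 1 and knockout 6 (8.2e-04). Glycolysis passed as higher without heterozygous 1 (adjusted p = 3.4e-04), without heterozygous 1 and knockout 6 (0.0139), with quantile (0.0236) or cyclic loess normalization (0.0419) and with the filter at the 60th percentile (0.0169). Their members with the smallest p included Xbp1 (4332 ± 547 and 3886 ± 589) and Atf4 (4260 ± 474 and 3866 ± 486), Cox7c (325.3 ± 29.99 and 427.3 ± 212.3) and Sdha (7290 ± 857 and 7740 ± 736), and Adm (1425 ± 60 and 1622 ± 169) and Aldoc (148.5 ± 50.8 and 116.0 ± 12.4).

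Interferon response and proliferation had the smallest p of all lists in the direction of higher expression in knockouts, and both calls were lost without knockout 4. On that array the thymus and T cell list also stood highest, with a median deviation of 0.77. With the sample numbers as a block interferon response (camera, adjusted p = 3.0e-04) and proliferation (9.9e-04) still passed, while the other 11 of the 13 called lists did not. A lost call was not always a smaller shift. The medians of thyroid hormone signalling (0.069) and immediate early genes (-0.082) were larger in size with the block. Of 21 interferon genes, 19 were higher, with a median of 0.23 (camera, adjusted p = 9.9e-06, and adjusted p = 0.611 with an estimated correlation). The immunoproteasome subunit Psmb8 read 329.7 ± 15.7 and 427.9 ± 77.6, and the antiviral gene Mx1 read 26.4 ± 8.0 and 102.1 ± 112.4. On knockout 4 Mx1 read 231.9, against 17.1 to 38.6 on the other arrays. Without knockout 4 the interferon median was 0.04 (adjusted p = 0.575). Of 28 proliferation genes, 25 were higher, with a median of 0.32 (camera, adjusted p = 1.0e-05, and adjusted p = 0.611 with an estimated correlation). The mitotic activator Cdc20 read 87.3 ± 28.2 and 137.1 ± 41.0, and Mcm7 of the replicative helicase read 747.0 ± 62.1 and 903.1 ± 115.2. The proliferation list's median per array was lowest on heterozygous 1, at -0.82, and highest on knockout 4, at 0.58. Without heterozygous 1 the median difference was -0.04 (adjusted p = 0.797), and without knockout 4 it was 0.05 (adjusted p = 0.394). It was 0.64 without heterozygous 3 and 0.50 without knockout 6, where the list passed.

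Markers of stroma, fat and blood-derived cells were slightly higher in knockout samples as groups. Collagen and extracellular matrix (16 of 22 higher, median 0.05, camera adjusted p = 0.00273), fibroblasts (12 of 15, 0.07, 0.00820), adipose tissue (12 of 15, 0.13, 0.00309) and macrophages and myeloid cells (15 of 20, 0.07, 0.0251) passed with the preset correlation. With an estimated correlation the adjusted p was 0.611 for the matrix, fibroblast and adipose lists and 0.679 for macrophages. Periostin (Postn) read 4354 ± 619 and 5117 ± 457, Fn1 read 3624 ± 457 and 4276 ± 607, Pi16 read 2325 ± 112 and 2814 ± 280, and Col14a1 read 1592 ± 262 and 1863 ± 101. In fat, Elovl3 had the smallest p, followed by Car3 (8631 ± 817 and 9733 ± 1080.1), while Ucp1, the uncoupling protein of brown fat, was abundant in all 6 samples at 10538 ± 677 and 10814 ± 1435. The macrophage protease Ctss read 2088 ± 243 and 2475 ± 120, and Ptprc read 599.2 ± 84.5 and 738.9 ± 175.9. All 4 calls were lost without knockout 4 (adjusted p = 0.354 for matrix, 0.410 for fibroblasts, 0.123 for fat and 0.588 for macrophages), with medians of 0.040, 0.0044, 0.069 and 0.025. They were also lost without heterozygous 1 for matrix (adjusted p = 0.0610), fibroblasts (0.140) and macrophages (0.907), without heterozygous 3 for fibroblasts (0.0964), fat (0.791) and macrophages (0.222), and without knockout 6 for fibroblasts (0.224), fat (0.661) and macrophages (0.625). Without heterozygous 1 the medians were 0.033 for matrix, 0.046 for fibroblasts, -0.026 for macrophages and, with the call kept, 0.064 for fat. Without heterozygous 3 the median of fat was 0.0013, and without knockout 6 the medians were 0.037 for fibroblasts, -0.0027 for fat and 0.011 for macrophages. All 4 lists passed with larger medians without knockout 2 (0.098 for matrix, 0.14 for fibroblasts, 0.33 for fat and 0.18 for macrophages) and without heterozygous 5 (0.098, 0.18, 0.27 and 0.13). Without knockouts 4 and 6, which leaves knockout 2 alone, the medians of fat (-0.19) and macrophages (-0.12) were below 0. With the sample numbers as a block both lists were lower and did not pass (camera, median -0.046, adjusted p = 0.641 and -0.053, 0.526). The fat list's median per array was -0.14, -0.21 and -0.27 on samples 1 to 3 and 0.20, 0.21 and 0.32 on samples 4 to 6.

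Several thymus and T cell genes were far brighter on knockout 4 than on any other array. All 8 tested members had the higher knockout mean, with a median log2 difference of 0.41 (camera, adjusted p = 0.00296, and adjusted p = 0.611 with an estimated correlation). The list's median per array was 0.77 on knockout 4. On knockouts 2 and 6 it was -0.48 and -0.42, below the -0.26, -0.39 and -0.35 on heterozygous 1, 3 and 5. Dntt, the terminal transferase of immature lymphocytes, read 1779 on knockout 4 and between 6.09 and 24.5 on the other arrays. The T cell receptor subunits Cd3g and Cd3d read 578.1 and 752.7 on knockout 4, and at most 28.6 and 30.7 elsewhere. Cd2, with the smallest p of the list, read 58.6 ± 7.86 and 97.0 ± 24.5. Without knockout 4 fewer than 5 members were left above the filter and the list had no test. Members that passed the filter only through knockout 4 had to have the higher knockout mean, so the count of 8 is no separate support. The list's median was 0.17 with 0.25 times the pseudocount and 0.74 without a filter. It lay between 0.62 and 0.65 without heterozygous 1, knockout 2 or knockout 6. The list passed in each of these settings, all of which keep knockout 4. Endothelial markers did not pass (17 genes, camera, adjusted p = 0.252), with Egfl7 at 1239 ± 122 and 1455 ± 231 and Vwf at 610.1 ± 204.5 and 463.7 ± 19.4. B cell markers had 4 tested genes and red blood cell markers 3, too few for a test. Blnk read 742.9 ± 166.4 and 599.4 ± 153.0, Cd79b read 371.2 ± 77.7 and 330.8 ± 77.3, and the red cell enzyme Bpgm read 1283 ± 91 and 1375 ± 172.

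Skeletal muscle transcripts were lower in knockout samples as a group, 22 of 27 with a median log2 difference of -0.66 (camera, adjusted p = 1.4e-04, and adjusted p = 0.611 with an estimated correlation). The fast troponin Tnni2 read 3567 ± 1159 and 2419 ± 2142, the fast myosin light chain Mylpf read 6425 ± 712 and 4564 ± 2454, and Tnnc2 read 3882 ± 1003 and 2761 ± 1345. Myoglobin (Mb), whose p was the smallest of the list, went the other way at 1355 ± 196 and 1740 ± 421. The list's median per array was -1.37 on knockout 6, -0.14 on knockout 4 and 0.90 on knockout 2, with 0.79, 0.18 and -0.06 on heterozygous 1, 3 and 5. Without knockout 6 the median difference was -0.05 (adjusted p = 0.981), and without heterozygous 1 it was -0.26 (adjusted p = 0.0610). Without knockout 2 it was -1.11 (adjusted p = 8.9e-10), and with the sample numbers as a block it was -0.21 (adjusted p = 0.0503). The list passed as higher without heterozygous 1 and knockout 6 (median 0.22, camera, adjusted p = 0.00315). Without knockouts 4 and 6, which leaves knockout 2 alone, its median was 0.52. C cell markers were lower too, 11 of 15 with a median of -0.12 (camera, adjusted p = 0.0131, and adjusted p = 0.654 with an estimated correlation). They included Pcsk1n (86.0 ± 23.6 and 48.6 ± 8.60) and Chgb (1280 ± 512 and 885.1 ± 446.3). The median of the C cell list was the value of Chga, which is also in the parathyroid list. That call was lost without heterozygous 1 (median -0.14, adjusted p = 0.797), knockout 4 (-0.31, 0.327) or knockout 6 (-0.12, 0.487). The list passed without knockout 2 (median -0.65) and without heterozygous 5 (-0.21). It turned to higher, without passing, without heterozygous 1 and knockout 6 (median 0.043) and without knockouts 4 and 6 (0.24).

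Parathyroid markers differed widely between single arrays and did not pass between genotypes (5 genes, camera, adjusted p = 0.881). The list passed as lower without heterozygous 1 (camera, adjusted p = 0.0164). Without knockouts 4 and 6, which leaves knockout 2 alone, its median was 1.11. Parathyroid hormone (Pth) read 165.2 on heterozygous 1 and 2788.5 on knockout 6, and between 9702 and 11058 on the other 4 arrays. Chga, shared by parathyroid and C cells, read 717.6 and 544.0 on the same pair and between 5631 and 6348 elsewhere. The transcription factor Tbx1 read 162.0 ± 23.5 and 134.8 ± 35.5. Smooth muscle and pericyte markers (9 of 12 lower, adjusted p = 0.0625), cartilage (9 genes, 0.881), airway, salivary and oesophageal epithelium (12 genes, 0.557) and nerve and Schwann cells (7 genes, 0.406) did not pass. Smooth muscle passed as lower without knockout 4 (camera, adjusted p = 0.0212), with the filter at the 60th percentile (0.0197) and with the block (0.0497). Nerve passed as higher without heterozygous 1 and knockout 6 (0.0280). Their members with the smallest p included Myh11 (275.4 ± 9.93 and 216.4 ± 34.1) and Des (467.9 ± 148.1 and 353.4 ± 65.7), Cnmd (34.2 ± 9.78 and 70.3 ± 34.2) and Epyc (833.3 ± 244.4 and 1129 ± 371). Tekt1 of cilia read 148.2 ± 36.6 and 225.5 ± 49.3, the keratin Krt4 read 93.2 ± 62.5 and 51.9 ± 13.7, L1cam read 288.4 ± 19.8 and 236.1 ± 12.2, and Ncam1 read 891.3 ± 201.4 and 769.6 ± 199.7.

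Knockout 6 was the only array with the transcripts of a female. Xist, which is expressed from the inactive X chromosome, read 5442 on knockout 6 and at most 110.2 on the others by probe set 1436936_s_at. The Y-linked genes Eif2s3y, Kdm5d and Uty read 9.12, 5.55 and 0.532 on knockout 6, and at least 3288, 427.0 and 444.7 on the others. Correlations of log2 values between arrays ran from 0.948 to 0.967 for knockout 6 against the others, and from 0.978 to 0.986 among the other 5. The measured neighbours of Slc26a4 on its chromosome that were fixed beforehand, 13 genes, had a median log2 difference of 0.08, with Bcap29 (985.2 ± 16.0 and 1108 ± 77) and Prkar2b (5836 ± 311 and 6394 ± 1067) at the smallest p.

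**Figure D3:**
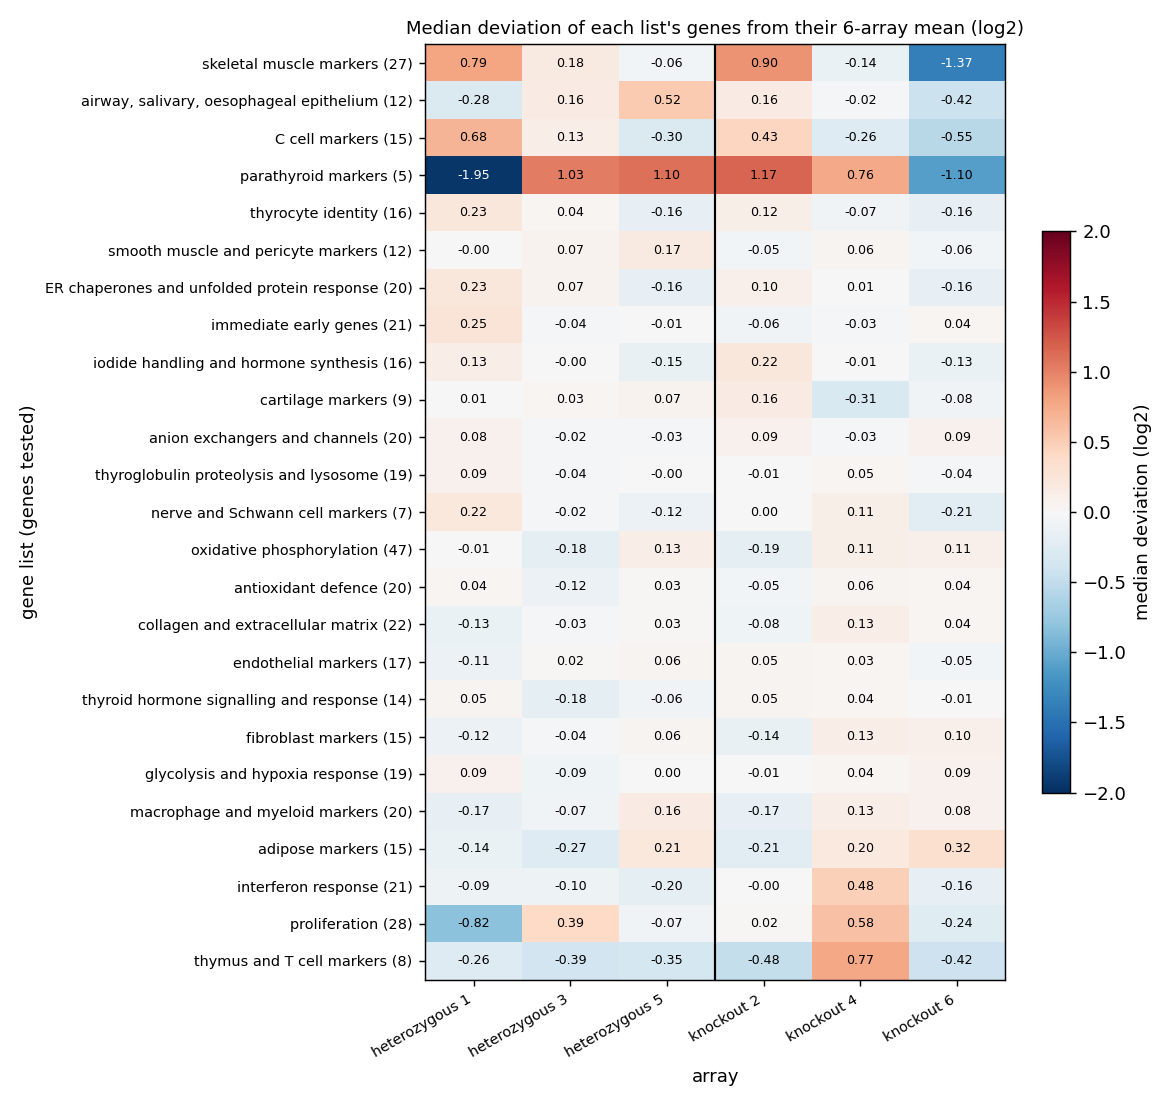
Median deviation of each tested list's genes from their mean over the 6 arrays, on the log2 scale, with the number of tested genes in brackets; heterozygous arrays stand left of the line and knockout arrays right of it. Skeletal muscle runs from 0.90 on knockout 2 to -1.37 on knockout 6, parathyroid is lowest on heterozygous 1 at -1.95, and thymus and T cell markers stand at 0.77 on knockout 4.

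**Figure D4:**
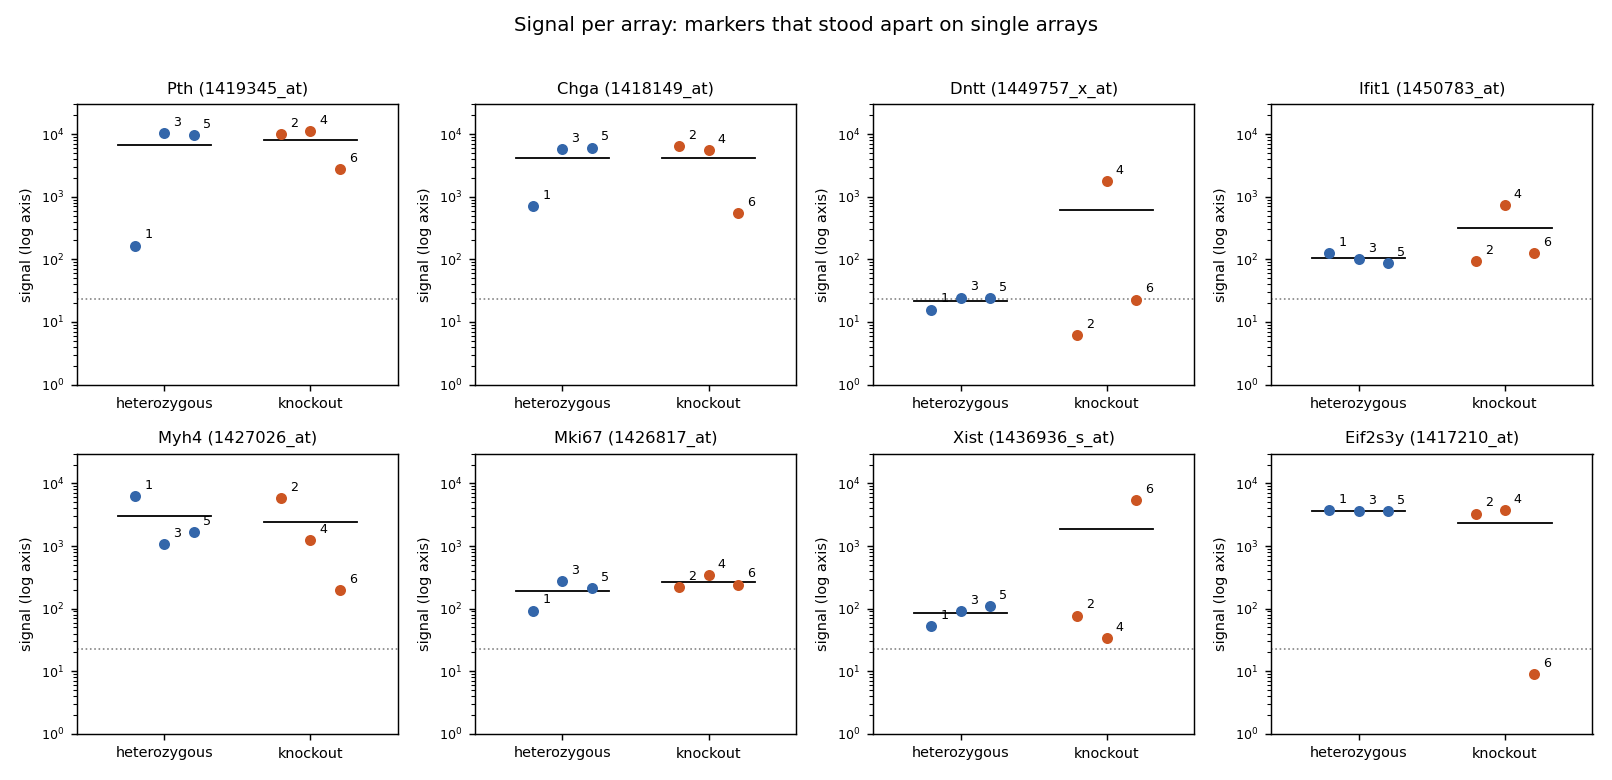
Signal per array (log axis) of Pth, Chga, Dntt, Ifit1, Myh4, Mki67, Xist and Eif2s3y, with heterozygous arrays in blue and knockout arrays in orange, numbered by sample; black bars are group means (n = 3 arrays) and the dotted line is the background of 22.9. Dntt stands at 1779 and Ifit1 at 733.2 on knockout 4, and Pth at 165.2 on heterozygous 1.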

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

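The tests that left out 2 arrays together or took the sample numbers as a block were chosen after the results were seen. The counts of 0 probe sets higher and 0 lower in limma stayed at 0 in all 18 alternative settings, with between 95 and 954 probe sets at an unadjusted p under 0.05 and a smallest adjusted p of 0.928, under array weights. None of the 159 named genes followed passed in any of them. Of their 2785 values, 172 had the opposite sign, none of them past the threshold, and 0 of the 415 values of the genes named for the smallest p did. Slc26a4 read under the background of 22.9 on all 6 arrays, so no setting tests its level, and signals near the background limit what can be said of other dim genes.

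The count of 13 lists past the threshold ran from 2 to 13 with 1 array left out, with 8 without heterozygous 3, 2 without knockout 4 and 6 without knockout 6. It was 7 without knockout 4 and knockout 6, 4 with the sample numbers as a block, and 0 both by camera with an estimated correlation and by fry. In the other settings it lay between 10 and 15. Lists that had not passed did so in their own direction 20 times, over 11 settings. Under array weights the medians of 9 called lists grew by more than 1.5 times and all 9 passed, as with proliferation (0.66), interferon response (0.46) and C cells (-0.50). The median of C cells was -0.33 with the filter at the 60th percentile and -0.23 with the mean of all probe sets, and that of matrix was 0.080 with the latter. Calls ended without a filter for thyrocyte identity (camera, adjusted p = 0.0524) and immediate early genes (0.0708), at the 60th percentile for the latter (0.158), under array weights for thyroid hormone signalling (0.0631), and with the mean of all probe sets for thyrocyte identity (0.0619), thyroid hormone signalling (0.184) and antioxidant defence (0.0505). With the block, 11 of the 13 calls were lost (camera, adjusted p = 0.904 for thyrocyte identity, 0.0503 for thyroid hormone signalling and for skeletal muscle, 0.145 for antioxidant defence, 0.109 for immediate early genes and for matrix, 0.770 for fibroblasts, 0.850 for C cells, 0.641 for adipose, 0.129 for thymus and 0.526 for macrophages). Of these lists, thyroid hormone signalling (median 0.069) and immediate early genes (-0.082) had medians larger in size with the block. The medians were smaller in size for thymus (0.32), skeletal muscle (-0.21), antioxidant defence (0.024), matrix (0.028), fibroblasts (0.029) and C cells (-0.073). Among lists past the threshold in the comparison itself or under the setting, camera's direction turned without heterozygous 1 for thyrocyte identity and immediate early genes and without heterozygous 3 for oxidative phosphorylation, whose medians with 1 array left out ran from -0.193 to -0.0099, from -0.108 to -0.017 and from -0.038 to 0.116. Of the called lists with 1 array left out, the median alone was below 0, with camera's direction kept, without heterozygous 1 for proliferation and macrophages, without heterozygous 3 for thyroid hormone signalling and without knockout 6 for adipose. Without heterozygous 1 and knockout 6 camera's direction turned for thyrocyte identity (a median of 0.087), endoplasmic reticulum chaperones (0.090), C cells (0.043), skeletal muscle (0.22), macrophages (-0.084) and nerve (0.16), and 3 of these passed in the new direction (chaperones, muscle and nerve). Without knockout 4 and knockout 6 it turned for thyrocyte identity (0.079), antioxidant defence (-0.055), oxidative phosphorylation (-0.17), extracellular matrix (-0.012) and fibroblasts (-0.079). It turned there as well for C cells (0.24), parathyroid (1.11), skeletal muscle (0.52), adipose (-0.19) and macrophages (-0.12). With the block it turned for thyrocyte identity (-0.020), oxidative phosphorylation (-0.062), adipose (-0.046) and macrophages (-0.053), and oxidative phosphorylation passed as lower. Lists past the threshold in neither turned 52 times over all settings. Where arrays were left out, the smaller number of samples is part of the setting, and otherwise the cause was not tested.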

Other observations

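The tests of the skeletal muscle list, of the Gapdh ratio, of the neighbours of Slc26a4 and of the other splits of the arrays were chosen after the results they bear on had been seen. The comparison of unnamed with named probe sets after quantile normalization was set before its result was seen.

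Of the 10 ways to divide the 6 arrays into 3 and 3, the one with the most calls followed the sample numbers, not the genotype. The 10 ways are too few for a share under 0.05. At an unadjusted p under 0.05 in limma, the split by genotype had the fewest probe sets of the 10, with 138 against 468 to 4985. It gave 0 past the threshold, as did every other split except arrays 1 to 3 against arrays 4 to 6. That split gave 318 past the threshold. Of these, 258 were higher and 60 lower in samples 4 to 6, which points to a structure of the samples that the genotype does not describe. The axis of largest variance in a principal component analysis (48.5%) instead set knockout 6 apart, at 69.0 against -30.5 to 2.46 on the other arrays. Samples 1 to 3 against 4 to 6 were followed up because that division had the most calls of the 10. Its p-values below make no allowance for this choice and are descriptive only. The skeletal muscle markers Pvalb (means of 5453 and 633.3), Tcap (1029.9 and 156.0) and Atp2a1 (4554 and 1244) were lower in samples 4 to 6. Their log2 differences were -3.06, -2.38 and -1.86 (limma, adjusted p = 0.00464, 0.0421 and 0.0449). The skeletal muscle list had a median log2 difference of -1.16 (camera, adjusted p = 2.4e-06, and adjusted p = 0.538 with an estimated correlation). Of the 15 adipose markers 14 were higher in samples 4 to 6, with a median of 0.33, and 7 passed in limma (camera, adjusted p = 1.9e-09, and adjusted p = 0.341 with an estimated correlation). The adipocyte regulator Pparg read 1540.2 ± 28.4 in samples 1 to 3 and 2536 ± 210 in samples 4 to 6, and the lipase Lipe 726.0 ± 93.9 and 1291 ± 142 (limma, adjusted p = 0.0361 and 0.0376). In all, 11 lists passed for this division with the preset correlation and 0 with an estimated correlation. All 47 oxidative phosphorylation genes were higher, with a median of 0.25 and 6 past the threshold in limma (camera, adjusted p = 7.7e-20, and adjusted p = 0.402 with an estimated correlation). Macrophage markers (median 0.29, camera adjusted p = 2.5e-06, and adjusted p = 0.117 with an estimated correlation), fibroblasts (0.20, 3.5e-05 and 0.117), matrix (0.14, 0.00396 and 0.472) and thymus (0.66, 0.0388 and 0.620) were higher as well. The lists lower in samples 4 to 6 were skeletal muscle, thyrocyte identity with 1 of 16 genes higher and a median of -0.31 (camera, adjusted p = 2.0e-05, and adjusted p = 0.369 with an estimated correlation), C cells with 0 of 15 higher and -0.56 (3.0e-06 and 0.341), chaperones with 1 of 20 higher and -0.23 (2.6e-06 and 0.519) and iodide handling with 5 of 16 higher and -0.20 (0.0193 and 0.538). With this division as a block, the genotype comparison gave 0 probe sets past the threshold in limma and 254 at an unadjusted p under 0.05. Samples 1 to 3 hold 2 heterozygous arrays and 1 knockout, and samples 4 to 6 hold 1 heterozygous array and 2 knockouts, so the division is partly confounded with genotype. What the numbers stand for is not given in the sources used here.

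Camera called 13 lists with a preset correlation and 0 with an estimated correlation, where the estimate reached 0.70 for proliferation and 0.83 for oxidative phosphorylation. Of the 13 called lists, 12 had a test for each array left out, and all 12 lost the call without at least 1 of them. The thymus and T cell list had no test without knockout 4. Knockout 4 ended 11 of them, heterozygous 1 ended 8, knockout 6 ended 7, heterozygous 3 ended 6, and knockout 2 and heterozygous 5 ended 2 each.

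For the lower skeletal muscle list in knockouts, a candidate explanation is muscle taken with the gland in different amounts. Its markers share 0 of 30 genes with another list, and the fast myosin Myh4 read 6311 on heterozygous 1, 5888 on knockout 2 and 198.5 on knockout 6. The list's median per array ranged over 0.85 (log2) within the heterozygous arrays alone, while the knockout mean minus the heterozygous mean was -0.51 (0.30 ± 0.44 for heterozygous and -0.20 ± 1.14 for knockout, n = 3 arrays each). An exact two-sided permutation test of these medians gave p = 0.6, where 0.1 is the smallest that 3 against 3 can give. Of the knockout arrays 1 lay above and 2 below all heterozygous arrays, so the list did not move in 1 direction with genotype. The spread within the heterozygous arrays does not show its own cause. Genotype and dissection cannot be told apart with 3 arrays per group. The medians also divided by sample number, at 0.79, 0.90 and 0.18 on samples 1 to 3 and -0.14, -0.06 and -1.37 on samples 4 to 6.

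Unnamed probe sets, those with no gene symbol or with several, were brighter on knockout 6, the female sample, by 0.29 (log2) relative to named ones. On the other arrays this difference lay between -0.15 and 0.07. RNA degradation is argued against by the ratio of 3' to 5' Gapdh control signals, 1.38 on knockout 6 within 1.32 to 1.47 on the other 5 arrays. A background or scaling effect that follows brightness alone is argued against as well, since after quantile normalization the excess over named probe sets of the same mean was still 0.25, with -0.11 to 0.05 on the other arrays. The median signal of the unspiked bacterial controls was nevertheless highest on knockout 6, at 6.96 against 1.90 to 5.33. Background specific to unnamed probe sets, sex, the individual animal and unspliced RNA stay open and were not tested.

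Tmem18 lies near Slc26a4, and sequence from another strain retained around the targeted gene could move it and other neighbours in knockouts. The mean absolute t of the 49 other measured genes around Slc26a4 was 0.58, at the 34.3th percentile of windows of 49 neighbouring genes. This lies within the spread of windows elsewhere and does not settle whether the region has an effect. In limma 0 of the 49 had an unadjusted p under 0.05. Only 0.522% of the genes outside the region did, so that count carries little information. A variant that acts on Tmem18 alone, a difference in its probes and chance stay open.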
